A study of Solanum lycopersicum with 6 samples.

How the data were processed

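Small RNA was extracted from green-stage tomato fruit with RNAiso Plus after removal of polysaccharides and polyphenols with Fruit-mate, treated with DNase, purified on RNeasy columns, and 240 ng of total RNA went into libraries made with the NEBNext Multiplex Small RNA kit, per the labels' protocols. Plants grew in a greenhouse at 25 °C in a light period of 12 h and at 20 °C in the dark. The 6 samples were grouped by their treatment label into 3 drought and 3 control samples. The fertilizer was diluted 500-fold in both groups, so drought plants received less fertilizer as well as less water.

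The authors deposited 1 table with 137 rows, each a mature tomato miRNA, and per the file headers its columns give the total count of each miRNA in each sample and a CPM value. The counts are whole numbers with no normalization. The deposited CPM values are the counts divided by 1 constant per sample that is not the sample's total, so their scale is an effective library size; that constant equals the total times the TMM factor of the table without a filter (for example 1.056 in control library 1 and 1.223 in drought library 2). The same table gives the authors' own fold change, log2 fold change, p-value and adjusted p-values between drought and control, and the test behind them is not named in the header. The read trimmer, aligner, mismatch setting, miRNA database release and genome build are not given in the sources used here. If reads that match several miRNAs were given to 1 of them, close members such as miR159 and miR159b, or members of miR156, miR167, miR171 and miR482, can trade counts, so values of single members of these families are uncertain and families were tested as sums too. A kit that ligates adapters favours some miRNA ends over others, so CPM values compare 1 miRNA between libraries and not different miRNAs within a library. PCR copies are not marked, so intervals and floors cover counting error only.

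Total counts ran from 644434 to 749332 in control and from 430732 to 468711 in drought. A count of 0 allows up to 3 counts, 4.00 to 6.96 CPM depending on the library. Names were looked up in a gene table of assembly SLM_r2.1, which held the precursor of 126 of the 137 names. The build behind the deposited table is not given in the sources used here, so no coordinates are printed. That gene table gives miR5301 as a former name of MIR482e and miR4376 as a former name of MIR391, and both were counted in the Solanaceae list under their former names. No 2 libraries agreed within sampling noise: the chi-square per degree of freedom, over entries with at least 20 counts in the pair, was 50.1 or more.

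Counts were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood fit and test, robust, two-sided, group as the only term). Entries were kept by filterByExpr (minimum count 10, minimum total count 15), which left 99 miRNAs with 99.98% of all counts; of the 38 left out, 30 had a count. Libraries were scaled by TMM, with factors of 0.909, 1.00 and 0.963 in control and 0.848, 1.35 and 0.993 in drought. CPM values of miRNAs use these scaled library sizes, those of families use TMM factors of the family table, and the limits for a count of 0 use the unscaled totals. The common biological coefficient of variation was 0.393. P-values were adjusted by Benjamini-Hochberg and an adjusted p under 0.05 counted as passing. The standard error of a log2 fold change is its size divided by the square root of the quasi-likelihood F. Families were summed over all rows with the same number after miR and tested in the same way; the median prior degrees of freedom were 5.88 for miRNAs and infinite for families, so most families shared 1 estimate of the spread.

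In all, 11 lists were tested, all but the last with miRNA families fixed before the data were examined: auxin, copper, phosphate and sulfate, NB-LRR regulators, small RNA machinery, SBP and AP2, MYB and TCP, HD-ZIP III with NAC, GRAS and GRF, drought and abscisic acid, Solanaceae-restricted, and passenger strands. For the last only the rule was fixed before: its members are the arms with fewer total counts in this table, as in MIR167b with 176 counts of the 5p arm against 192 of the 3p arm. Lists by family hold both arms, and a passenger arm need not act on the targets for which its family is known. Each with at least 3 tested members was tested with camera of limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), with an estimated correlation and with fry as alternatives. The composition of the libraries was compared with exact permutation tests over all 20 assignments of the libraries to the groups. The rule for naming miRNAs, also fixed before, took every miRNA past the threshold if at most 24 passed, the 5 with the highest mean CPM, the 2 most abundant tested members of each list and any that passed in all 6 fits without 1 library; 36 were named. miR399b, miR171b-3p, miR171e, miR172a, miR172d, miR394-3p, miR393, miR827 and the 8 entries at 0 were added after their values were seen.

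The tests were run on simulated data first. With 99 miRNAs and the real means and library sizes, the edgeR test found 23.6% of miRNAs changed 2-fold and 89.7% of those changed 4-fold over 20 simulated data sets, 4.60% of its calls were false, and 5 of 20 sets without a change had a call. With 52 families it found 28.1% and 91.1%, 3.08% of calls were false, and 1 of 20 unchanged sets had a call. The list test found a 4-fold fall of the SBP and AP2 list in 20 of 20 sets and called it in 0 unchanged sets. Entries were drawn independently there, while the real list holds both arms of some precursors. The real change of the list was also smaller than 4-fold, with a median log2 fold change of -1.53, so these rates need not hold for the real data.

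Alternatives were DESeq2 1.42.0 size factors, library totals alone, upper-quartile scaling, no filter, a mean CPM of at least 10, DESeq2's own test, limma voom, the replicate number as a block, identical rows merged, the most abundant entry left out and each library left out in turn. The authors' effective library sizes were added as an alternative after seeing the data. For thinning, the counts of each entry were drawn binomially so that each library had the smallest total on average, and the draws were tested both with the filter applied anew and, as a choice made after the results were seen, with the same 99 miRNAs. Tables were read with pandas 2.3.3 in Python 3.11.15 and figures drawn with matplotlib 3.10.9. Prediction of target sites in cell wall genes, the subject of the series title, was planned but needs mature sequences and transcripts, which are not used here.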

Results

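Small RNA was sequenced from green-stage fruit of tomato (Solanum lycopersicum) to ask which microRNAs (miRNAs), the short RNAs that guide cleavage or repression of matching mRNAs, change when the plants receive less water. From flowering on, control pots received diluted liquid fertilizer and plain water on alternating days, while drought pots received the diluted fertilizer a single time each week. Each group had 3 libraries, and 137 mature tomato miRNAs were counted in each. The labels do not say whether the 3 libraries of a group came from separate plants, so p-values measure only the spread between these libraries, which may be technical. Names are those of the count table without the species prefix sly-.

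The drought libraries held fewer miRNA counts than the control libraries, and 5 entries held over 50% of the counts in each library. Totals are sums over the listed miRNAs, and the number of all reads is not given in the sources used here. The totals therefore cannot tell shallower sequencing from a smaller share of miRNA reads. Control libraries held 661605, 644434 and 749332 counts and drought libraries 442949, 468711 and 430732, so that the mean was 685124 ± 56265 in control against 447464 ± 19388 in drought (SD, n = 3 each; exact two-sided permutation p = 0.1, the smallest that 3 against 3 allows). The most abundant entry was miR159, which targets GAMYB-like transcription factors, in control library 1 and drought libraries 2 and 3. In control libraries 2 and 3 it was miR162, which targets the Dicer-like gene that makes miRNAs, and in drought library 1 it was miR10532. The top entry took 18.6% ± 0.864 of the counts in control and 17.2% ± 1.5 in drought (SD, n = 3 each; exact permutation p = 0.3), and the 5 most abundant entries together took 55.0% ± 3.15 and 54.4% ± 1.97 (exact permutation p = 1). A count was recorded for 120 ± 2.0 entries in control and 120 ± 3.1 in drought (exact permutation p = 1). The less abundant arms of precursors with both arms listed took 3.73% ± 0.122 of the counts in control and 6.36% ± 3.88 in drought (exact permutation p = 0.4), where drought library 1 alone reached 10.6%. For 8 entries (miR5302a, miR319d, miR10541, miR10535b and miR169a to miR169d) the count was 0 in all 6 libraries, which allows up to 0.883 CPM (counts per 1e+06 counts) over all libraries together, counting error only.

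Relative to the scaled miRNA counts of each library, drought fruit held less miR164a, less of most miR156 entries and less miR159b. It held more miR9474, miR394-5p, miR395a and miR399. miR164a-5p, which targets NAC-domain transcription factors, fell from 8638 ± 2666 CPM in control to 1282 ± 262 in drought (SD, n = 3 each), 6.74-fold, a log2 fold change of -2.75 ± 0.36 (SE; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0009). miR159b, among the most abundant entries in control fruit, fell from 81712 ± 21059 to 16418 ± 9305 CPM, a log2 fold change of -2.32 ± 0.49 (edgeR adjusted p = 0.0095). miR9474-5p, for which no target is named here, rose from 17.1 ± 4.32 to 505 ± 244 CPM, a log2 fold change of 4.86 ± 0.55 (edgeR adjusted p = 0.000532). miR394-5p, which targets an F-box gene of the LEAF CURLING RESPONSIVENESS type, rose from 166 ± 63.1 to 723 ± 436 CPM, a log2 fold change of 2.12 ± 0.51 (edgeR adjusted p = 0.0176). Drought library 2 held 1223 CPM of it, against 426 and 519 in drought libraries 1 and 3, and without drought replicate 2 the log2 fold change was 1.35 (edgeR adjusted p = 0.00692). It passed in 14 of 17 other settings, and leaving out control replicate 2 (edgeR adjusted p = 0.0752) or control replicate 3 (0.0757) was among those that ended the call (adjusted p from 0.000323 to 0.0757 over all 17).

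Of 99 miRNAs with enough counts to test, 20 passed an adjusted p of 0.05 in the edgeR quasi-likelihood test, 9 that rose and 11 that fell, and 34 had an unadjusted p under 0.05. In all 20 the 3 drought libraries lay on 1 side of the 3 control libraries. This held for 37 of the 99 tested miRNAs, where chance gives 10%. The rises were miR9474-5p, miR9474-3p, miR171b-5p, miR394-5p, miR399, miR395a, miR391, miR482e-5p and miR1918, and the falls miR164a-5p, miR164a-3p, miR156a, miR156d-5p, miR156d-3p, miR156e-5p, miR167b-3p, miR167b-5p, miR159b, miR172c and miR403-3p. Log2 fold changes of the falls ran from -3.56 ± 0.69 for miR167b-3p to -1.16 ± 0.35 for miR403-3p. Both arms of miR167b rested on few drought counts, 0, 6 and 5 for the 3p arm and 1, 11 and 5 for the 5p arm. A pair of the rises rested on few control counts. miR9474-3p had counts of 1, 0 and 1 in control and 9, 79 and 17 in drought, a ratio of 72.0 between the summed scaled counts (exact 95% Poisson interval 19.4 to 602, counting error only), and miR171b-5p had 2, 1 and 0 against 21, 10 and 21, a ratio of 23.8 (7.69 to 119). After all libraries were thinned to 430732 counts in 20 draws, the filter on low counts kept miR9474-3p in 0 draws and miR171b-5p in 3. With the same 99 miRNAs tested in each draw, both passed in 20 of 20, with a median log2 fold change of 5.89 and 4.39.

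**Figure D1:**
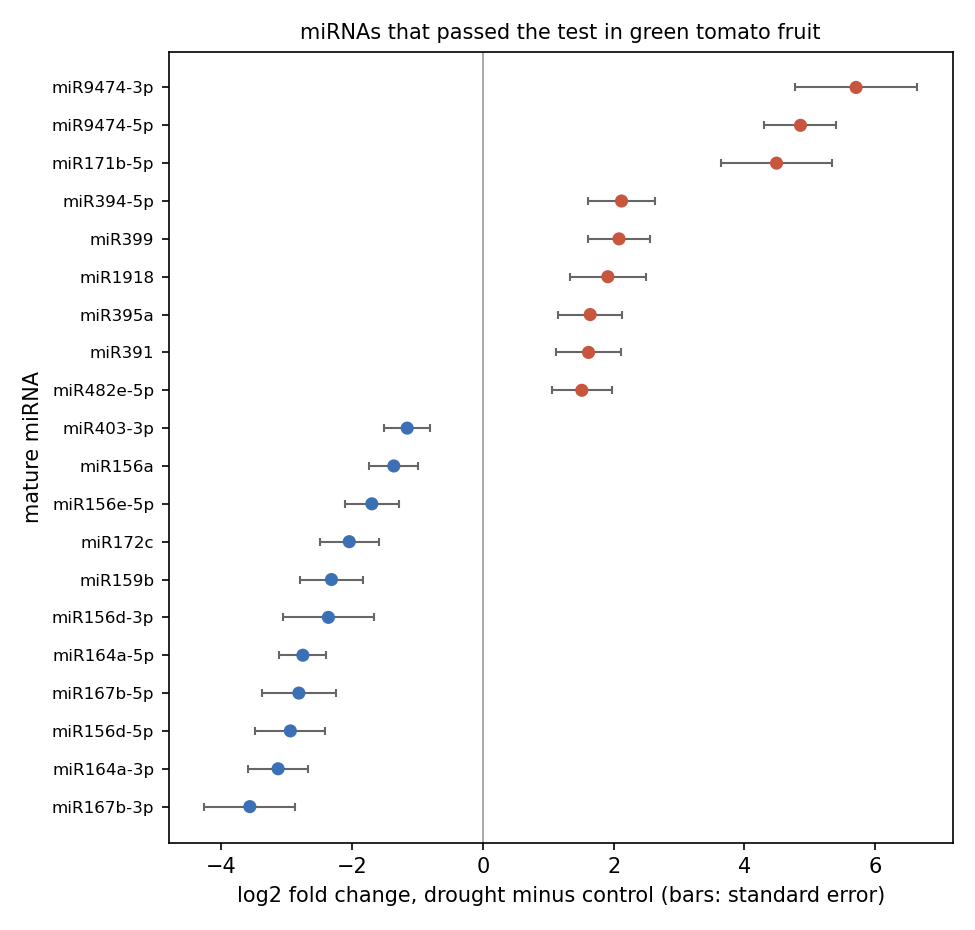
Log2 fold change, drought minus control, of the 20 miRNAs that passed the edgeR test (x axis, log2 units; bars, standard error; 3 libraries per group; red rose, blue fell). Falls reached -3.56 (miR167b-3p, which rests on drought counts of 0, 6 and 5). Rises reached 5.71 (miR9474-3p, which rests on 2 control counts, while miR171b-5p rests on 3).

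The scaling changed the balance of rises and falls. With library totals alone 16 rose and 11 fell, and with upper-quartile scaling 16 rose and 10 fell. The median log2 fold change of all tested entries, 0.16 with TMM scaling, was 0.27 and 0.40 in these fits. Of the 20 miRNAs, 19 still passed in each, the exception being miR403-3p. Leaving out single libraries moved the count itself: without control replicate 2 there were 9 miRNAs, without control replicate 3 there were 13 and without drought replicate 2 there were 41. Of the 20, the number that still passed was 16, 9 and 12 without control replicates 1, 2 and 3, and 14, 20 and 16 without drought replicates 1, 2 and 3. Without drought replicate 2, miR162, miR10532, miR408, miR7981e, miR9471a-3p, miR396a-3p and miR166c-5p passed too, and without drought replicate 3 so did miR167a. The 8 that passed in each of these 6 fits were miR9474-5p, miR9474-3p, miR164a-5p, miR164a-3p, miR156d-5p, miR171b-5p, miR167b-3p and miR159b. miR403-3p passed in 7 of 17 other settings and did not pass in the other 10, such as library totals alone (log2 fold change -1.01, edgeR adjusted p = 0.0874; adjusted p from 0.00454 to 0.358 over all 17).

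**Figure D2:**
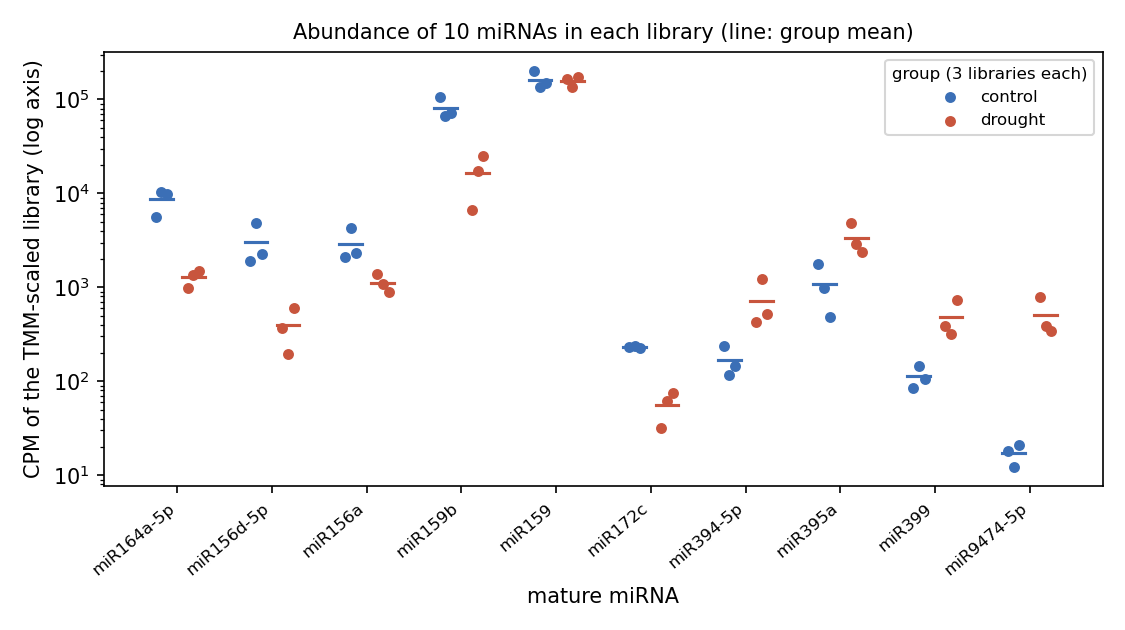
CPM of 10 miRNAs in each library on a log axis (points, libraries; lines, group means; blue control, red drought; 3 libraries each). The drought libraries of miR164a-5p lie between 990 and 1498 CPM and those of control between 5580 and 10473, while the libraries of miR159 overlap.

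Among miRNAs linked to the timing of phase change, the list of miR156, which targets SBP-box transcription factors, and miR172, which targets AP2-like ones, held 5 falls and 0 rises in 8 tested members, and also 5 falls when adjusted over the list alone. Of the 5, miR156d-3p is the less abundant arm of its precursor. Without control replicate 2 only miR156d-5p of the 5 passed, and 4 and 3 of them passed without control replicates 1 and 3, and 4, 5 and 3 without drought replicates 1, 2 and 3. miR156d-5p went from 3022 ± 1622 to 393 ± 207 CPM (SD, n = 3 each), a log2 fold change of -2.94 ± 0.53, and miR156a from 2882 ± 1179 to 1122 ± 243, a log2 fold change of -1.36 ± 0.38 (edgeR adjusted p = 0.0336; -0.84 and adjusted p = 0.288 without control replicate 2, the highest of all settings). miR172c went from 233 ± 6.27 to 56.1 ± 21.9 CPM, a log2 fold change of -2.04 ± 0.45 (edgeR adjusted p = 0.0106; 0.0560 without control replicate 2, the highest of all settings), while the other tested miR172 members, miR172a at 0.16 ± 0.52 and miR172d at 0.54 ± 0.37, did not pass. The list was the 1 of 11 to pass camera's test against the other miRNAs with its preset correlation of 0.01 (adjusted p = 0.0360). With an estimated correlation it did not pass (camera adjusted p = 0.368). The estimate was -0.096, so the loss did not come from a positive correlation of the members.

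miRNAs that respond to phosphate and sulfate supply had the highest median change of the lists, 1.75 on the log2 scale, and all 4 tested members had a positive log2 fold change. miR399, which targets the ubiquitin-conjugating enzyme PHO2, rose from 113 ± 31.5 to 479 ± 225 CPM (log2 fold change 2.08 ± 0.47, edgeR adjusted p = 0.0123), and miR395a, which targets ATP sulfurylase and sulfate transporter genes, rose from 1079 ± 646 to 3365 ± 1256 (1.64 ± 0.49, edgeR adjusted p = 0.0428). Without control replicate 1 miR399 did not pass (edgeR adjusted p = 0.0574), and miR395a did not pass without control replicate 2 (0.105), control replicate 3 (0.130) or drought replicate 1 (0.0680). Over all 17 other settings miR399 passed in 15 and miR395a in 14. These were 2 rises among 4, with 3 rises when adjusted over the list alone, the further 1 being miR399b. As a set the 4 did not pass camera (adjusted p = 0.0856, and 0.368 with an estimated correlation, which was -0.097). The set passed without control replicate 2 (camera adjusted p = 0.0466) and without drought replicate 3 (0.0487), but not without any other library. In the list of copper-linked miRNAs, 0 of 4 tested members passed, also when adjusted over the list alone (edgeR; camera adjusted p = 0.921), and 1, miR408, had an unadjusted p under 0.05. miR408, which targets plantacyanin and laccase genes, stood at 1.55 ± 0.60 (edgeR adjusted p = 0.0928), passing with DESeq2, library totals alone, upper-quartile scaling and without drought replicate 2, and miR398a, which targets a copper/zinc superoxide dismutase, at -0.59 ± 0.64. The median of the copper list was -0.13, its mean 0.18, and camera's direction was up.

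Among regulators of auxin signalling, both arms of miR167b, which targets auxin response factors, fell, and the more abundant miR167a did not pass. miR167b-5p went from 80.1 ± 24.4 to 10.6 ± 7.41 CPM and miR167b-3p from 90.1 ± 37.9 to 7.05 ± 6.21 (SD, n = 3 each), while miR167a stood at 3055 ± 160 and 6455 ± 3096 CPM, a log2 fold change of 1.08 ± 0.38 (edgeR adjusted p = 0.0787), and miR160a, another regulator of auxin response factors, at 0.63 ± 0.42. The list held 2 falls and 0 rises among 7 tested members, and 2 falls and 1 rise, miR167a, when adjusted over the list alone (camera adjusted p = 0.921). Its median was 0.25 and its mean -0.56, and camera's direction was down. miR167a passed with library totals alone, with upper-quartile scaling and without drought replicate 3, and miR167b-5p did not pass without control replicate 2 (edgeR adjusted p = 0.0560, the highest of all settings). Drought library 2 held 9519 CPM of miR167a, against 6517 and 3329 in drought libraries 1 and 3. The log2 fold change of miR167a ran from 0.54 to 1.46 when 1 library was left out.

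In the list of miRNA families that regulate HD-ZIP III, NAC, GRAS and GRF transcription factors, both arms of miR164a fell and miR171b-5p rose, among 14 tested members. Of these, miR164a-3p and miR171b-5p are the less abundant arms of their precursors, and the other arm of the latter, miR171b-3p, stood at 1.25 ± 0.40 (edgeR adjusted p = 0.0529). miR164a-3p went from 2935 ± 1134 to 335 ± 132 CPM (edgeR adjusted p = 0.00201). The abundant members did not pass: miR166a, which targets HD-ZIP III genes, stood at 0.21 ± 0.31 and miR396b, which targets growth-regulating factors, at -0.44 ± 0.35 on the log2 scale. Adjusted over the list alone there were 2 falls and 2 rises, the further rise being miR171b-3p (camera adjusted p = 0.921). The median of the list was 0.40 and its mean 0.05, and camera's direction was down. Without drought replicate 2 there were 3 falls and 3 rises, and without drought replicate 1 there were 2 of each. In the MYB and TCP list, miR159b fell while the more abundant miR159 stood at -0.03 ± 0.32, a value that turned positive with library totals alone (0.11), upper-quartile scaling (0.19) and no filter (0.02). That was 1 fall among 5 tested members, also when adjusted over the list alone (camera adjusted p = 0.914), and 2 without drought replicate 2.

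The list of miRNAs reported as responsive to drought or abscisic acid in several plants did not pass camera, which tests for a shared direction. It passed fry's test without regard to direction, against no change in any member (adjusted p = 0.00295). So did all other lists but copper, NB-LRR and small RNA machinery. Of its 10 tested members, miR394-5p rose and miR159b fell, the same count as adjusted over the list alone (camera adjusted p = 0.914), with a median of -0.47. The rise was lost without control replicate 2 or 3, and without drought replicate 2 there were 3 rises and 2 falls. Among regulators of the small RNA machinery, miR403-3p, which targets an Argonaute gene, went from 3943 ± 1508 to 1768 ± 151 CPM (edgeR adjusted p = 0.0428), the 1 fall among 6 tested members and also the 1 adjusted over the list alone (camera adjusted p = 0.914). miR162 stood at 165429 ± 45967 CPM in control and 69569 ± 41892 in drought, a log2 fold change of -1.25 ± 0.54 that did not pass (edgeR adjusted p = 0.128), and miR168a-5p, which targets another Argonaute gene, at 0.03 ± 0.27. miR162 passed with library totals alone, with DESeq2 and without drought replicate 2. The fall of miR403-3p was lost without control replicate 2 or 3 and without drought replicate 1 or 3.

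In the list of 11 tested members of families that regulate NB-LRR resistance genes 1 rose, miR482e-5p, the less abundant (passenger) arm of its precursor, from 893 ± 376 to 2551 ± 1079 CPM (edgeR adjusted p = 0.0428), and 0 passed when adjusted over the list alone (camera adjusted p = 0.921). The abundant arm miR482e-3p stood at -0.25 ± 0.32 and miR482b at 0.19 ± 0.31. The largest list, of families taken as Solanaceae-restricted, had 34 tested miRNAs, among them miR482e-5p and miR391 only by their former names miR5301 and miR4376. That list held 5 rises and 0 falls, and 2 rises, miR9474-5p and miR9474-3p, when adjusted over the list alone (camera adjusted p = 0.205). Besides these and miR482e-5p, the rises were miR391, formerly miR4376, which targets an autoinhibited calcium ATPase and went from 67.1 ± 28.6 to 206 ± 79.8 CPM, and miR1918, from 14.9 ± 8.55 to 56.2 ± 26.4 CPM. miR391, miR482e-5p and miR1918 passed in 12, 12 and 11 of 17 other settings, and all 3 calls were lost together without control replicate 2, control replicate 3 or drought replicate 1, which left 2 rises in this list and 0 in the NB-LRR list. Without control replicate 1 the list had 3 rises, without drought replicate 2 it had 10 rises and 4 falls, and without drought replicate 3 miR482e-5p was lost. The abundant miR7981e stood at 1.03 ± 0.45 (edgeR adjusted p = 0.132), passing with library totals alone and without drought replicate 2, and miR9471a-3p at -0.44 ± 0.38, passing without drought replicate 2. miR10532, which belongs to no list, stood at 1.15 ± 0.44 (edgeR adjusted p = 0.0928), and it passed with library totals alone, with upper-quartile scaling and without drought replicate 2. Among 19 tested passenger strands, taken as the arms with fewer counts in these libraries, miR9474-3p, miR171b-5p and miR482e-5p rose and miR164a-3p, miR156d-3p and miR167b-5p fell, 3 rises and 3 falls, also when adjusted over the list alone (camera adjusted p = 0.921). Their median was -0.09 and their mean 0.25, and camera's direction was down. The abundant passenger strands did not pass: miR396a-3p stood at 1.24 ± 0.60 and miR166c-5p at 0.77 ± 0.66, both highest in drought library 1. When 1 library was left out, miR396a-3p ran from 0.30 to 1.55 and miR166c-5p from -0.24 to 1.12. Without drought replicate 2 both passed and there were 5 rises and 3 falls, and without control replicate 2 there were 2 rises and 1 fall.

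Reads of near-identical family members can be assigned to any of them, so counts were also summed by family. Families miR9474, miR394, miR399, miR395, miR391, miR1918, miR408, miR10532, miR5302, miR167 and miR7981 rose and families miR164, miR156, miR403, miR162 and miR10537 fell. Family miR164 went from 11798 ± 4035 to 1629 ± 469 CPM (SD, n = 3 each), a log2 fold change of -2.86 ± 0.38, and family miR156 from 7038 ± 3079 to 1811 ± 304, a log2 fold change of -1.96 ± 0.36. Family miR399 went from 179 ± 46.8 to 710 ± 290 CPM, a log2 fold change of 1.98 ± 0.40. Some families did not follow their called member: miR159 summed to 246244 ± 48747 CPM in control and 174430 ± 37853 in drought (edgeR adjusted p = 0.327), miR172 stood at -0.62 ± 0.41, miR171 at 0.23 ± 0.38 and miR482 at -0.09 ± 0.38, and family miR167 stood at 0.94 ± 0.35 (edgeR adjusted p = 0.0312). The family miR167 call was held in 6 of 15 other settings and was lost, among others, with library totals, no filter, DESeq2 and limma voom, without control replicates 2 and 3 and without drought replicates 1 and 2 (0.41, edgeR adjusted p = 0.464 without drought replicate 2, the highest of all settings). Of 52 families tested, 16 passed, 11 that rose and 5 that fell, and 21 had an unadjusted p under 0.05. The family fit used a common spread for most families: for miR395, with 1 member listed, the edgeR adjusted p was 0.00059 in the family fit and 0.0428 in the miRNA fit, and limma voom called 10 of the 16. Families miR9474, miR164, miR156, miR394 and miR399 passed in all 15 other settings, the other 11 in 3 (miR10537) to 13 (miR391 and miR395), and no called family changed sign in any of them. The count was 14, 6 and 5 without control replicates 1, 2 and 3, and 9, 22 and 15 without drought replicates 1, 2 and 3.

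The log2 fold changes of the 5p and 3p arms cut from the same precursor mostly had the same sign, most clearly where an arm passed the test. Of 19 precursors with both arms tested, 14 had the same sign in both, and in MIR9474, MIR164a, MIR156d and MIR167b both arms passed the test. Of 8 precursors with a called arm 7 had the same sign in both, and the exception was MIR482e, whose 5p arm rose while its 3p arm stood at -0.25 ± 0.32. Across precursors, which are not independent replicates, the log2 fold changes of the arms had a Pearson r of 0.853 (permutation p = 1e-05, the smallest that 100000 permutations can give; Benjamini-Hochberg adjusted p = 2e-05 over both coefficients) and a Spearman rho of 0.754 (permutation p = 0.00025, adjusted p = 0.00025). Without the 2 precursors farthest from the median 5p change, r was 0.804 (permutation p = 0.00029) and rho 0.657 (permutation p = 0.00473). The called pairs MIR164a, MIR156d and MIR167b stayed in, and no correlation was computed for the precursors without a called arm alone. The comparison of arms was added after the values were seen.

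**Figure D3:**
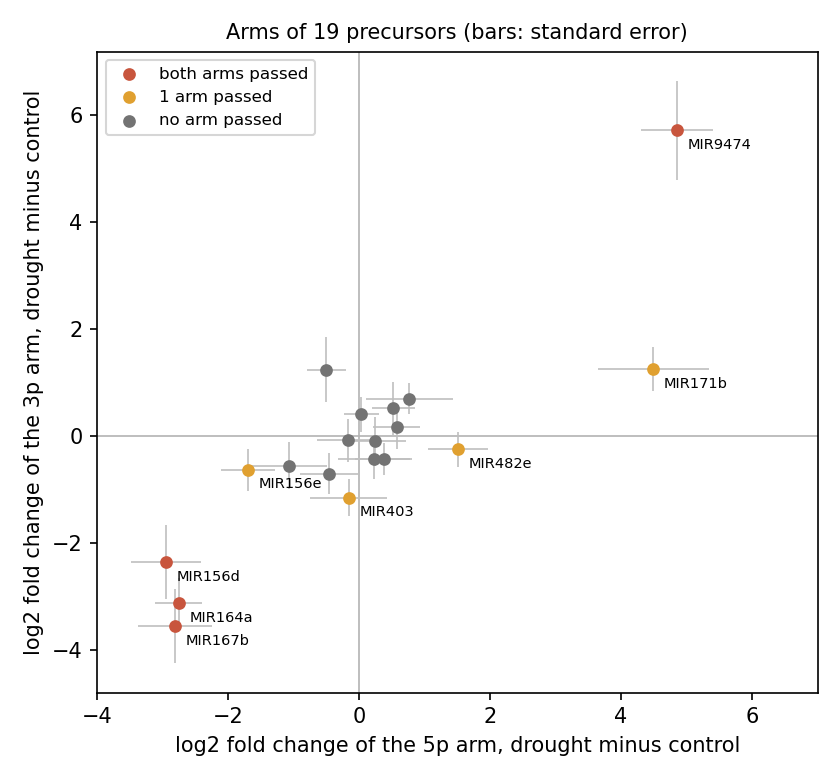
Log2 fold change, drought minus control, of the 5p arm (x axis) and the 3p arm (y axis) of 19 precursors (points, precursors; bars, standard error; red both arms passed, orange 1 arm, grey none). The called pairs MIR164a, MIR156d and MIR167b lie at the lower left and MIR9474 at the upper right.

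The authors' deposited table gives its own fold changes and adjusted p-values for 129 rows with a count. In it, 32 rows have an adjusted p under 0.05, 18 with a positive and 14 with a negative log2 fold change. All 20 miRNAs that passed here are among the 32 of the authors' deposited table, 11 others were tested here and did not pass, and 1, miR394-3p, was not tested here. The log2 fold change had the same sign in 98 of the 99 miRNAs tested here and in the authors' deposited table, and the largest difference between them was 0.15. Both use the same counts with TMM scaling, so this closeness was largely fixed beforehand and is not separate evidence.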

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

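The authors' library sizes were chosen as an alternative after the data were seen, and the others before. All 20 miRNAs that passed kept their direction in all 17 other settings and 8 of them passed in each. The number of miRNAs past the threshold, 20, was 21 with DESeq2 size factors or no filter, 22 with a mean CPM of at least 10 or the authors' sizes, 23 without the most abundant entry, 26 with DESeq2 or upper-quartile scaling, 27 with library totals and 17 with limma voom, and ranged from 9 to 41 when 1 library was left out. Merging identical rows changed no tested entry and says nothing, yet it counts as 1 pass for each of the 20 in the tallies over 17 settings. Families, 16, went to 10 with limma voom, ranged from 5 to 22 without 1 library, and lay between 13 and 16 with the other scalings, filters and DESeq2. Of the lists, 1 passed, and 0 did with an estimated correlation. With fry, which tests a list against no change and not against other miRNAs, 2 passed in a shared direction (SBP and AP2, and phosphate and sulfate). Without regard to direction, all lists but copper, NB-LRR and small RNA machinery passed fry. Without 1 library, 1 to 2 lists passed camera. Deviations of same-numbered libraries correlated at r = 0.10, -0.24 and 0.01, and not every sample correlated best with its own number. With 3 libraries per group these values gave no clear sign of pairing but cannot exclude it. With a replicate block, a fit with fewer residual degrees of freedom, 12 miRNAs, 6 families and 0 lists passed (SBP and AP2 camera adjusted p = 0.0523). In that fit miR399, miR394-5p, miR156a, miR156e-5p, miR156d-3p, miR403-3p, miR391 and miR1918 did not pass.

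Values near 0 changed sign, and so did the larger one of miR166c-5p. miR168a-5p, 0.03, was -0.0273 with DESeq2 size factors or DESeq2 and -0.0278 with a mean CPM of at least 10, and ran from -0.0703 to 0.171 without 1 library. miR159, -0.03, was 0.11 with library totals, 0.19 with upper-quartile scaling and 0.0235 with no filter or the authors' sizes, and ran from -0.0856 to 0.150 without 1 library. miR166c-5p, 0.77, ran from -0.24, without drought replicate 1, to 1.12. The difference in the share of the top 5 entries ran from -2.20 to 0.945 percentage points and that in entries with a count from -1 to 2. The cause of these changes was not tested. The alternatives for files without counts did not apply. Target sites in cell wall genes, with their score limits and keyword list, were not run. Low counts limit the precision of the ratios of miR9474-3p and miR171b-5p, which rest on 2 and 3 control counts. They also limit the falls of both miR167b arms, which rest on few drought counts.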

Other observations

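Of the tests below, those on scaling, on shared reads and on nutrient supply, thinning with the tested miRNAs held fixed, and the arm and member ratios, were chosen after the results were seen. Of 6 pairs of family members or arms compared within libraries, a measure that needs no scaling, the drought libraries lay on 1 side of the control libraries in 4. The pairs were picked with their fold changes known, so this count is not separate evidence. The log2 ratio of miR159b to miR159 counts was -0.998 ± 0.072 in control and -3.47 ± 1.0 in drought (SD, n = 3 each; exact two-sided permutation p = 0.1, the smallest possible). The ratio of miR167b-5p to miR167a went from -5.29 ± 0.48 to -9.24 ± 1.34, and that of miR171b-3p to miR171e, both regulators of GRAS genes, from -3.67 ± 0.94 to 0.07 ± 1.61 (exact permutation p = 0.1 for each, 0.5 added to each count). Within precursor MIR396a the 3p to 5p ratio was 1.59 in drought library 1, the 1 library in which the 3p arm had more counts, against -1.42 and -0.20 in drought libraries 2 and 3 and -1.33 ± 0.39 in control (exact permutation p = 0.2 between groups). The 5p to 3p ratio in MIR482e went from -5.19 ± 0.45 to -3.46 ± 0.56 (exact permutation p = 0.1), and that in MIR166c from -1.20 ± 0.23 to -1.70 ± 1.59 (exact permutation p = 0.8).

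Some entries outside the filter had few counts. miR394-3p had 2, 0 and 0 counts in control and 8, 15 and 6 in drought, a ratio of 19.9 (exact 95% Poisson interval 5.03 to 172, counting error only), and its other arm miR394-5p rose. miR393, which targets auxin receptor genes of the TIR1 type, had 5, 0 and 3 counts against 22, 9 and 2. Drought library 2 stood apart from the others of its group: on the second principal component, 20.0% of the variance, it lay at 7.33 and drought libraries 1 and 3 at -4.33 and -2.35, while the first, 65.9%, separated all drought from all control libraries.

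For the 20 miRNAs that passed between the groups, lower total counts and scaling were weighed. After thinning to 430732 counts per library, a median of 17 of the 20 still passed over 20 draws (12 to 19). With the same 99 miRNAs tested in each draw the median was 19 (14 to 20). The test already scales by library size and most of the 20 kept many counts, so most were likely to pass again. The draws show only that few calls needed the higher control totals. They cannot weigh differences in RNA quality or library yield between the groups. With library totals, upper-quartile scaling or the most abundant entry left out, 19 or more of the 20 still passed, so few calls hung on these choices. The entry left out, miR159, had itself hardly changed (log2 fold change -0.03). The abundant miR162, miR159b and miR10532 stayed in, so a shift of the scaling made by them was not tested by leaving them out. Of the 10 ways to split the 6 libraries into 3 and 3, only the real one, 1 of 10, gave 20 miRNAs or 16 families and the highest other gave 0 of either; for the lists 2 of 10 splits gave 1, with 1 the highest other, and 10 splits are too few for a share under 0.05. Differences in fruit age or size between the groups were not tested and stay open beside the watering.

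The fall of miR159b beside miR159 may reflect a real parting of the members or reads of miR159b counted under miR159 in drought libraries. miR159b passed in 20 of 20 thinned draws. With 2511 or more counts in each library that outcome was nearly certain beforehand, so the draws do not weigh on the cause. If the reads had moved, miR159 should have gained about the 65293 CPM that miR159b lost. Its mean changed by -3205 CPM, but with 3 libraries per group the 95% interval ran from -71127 to 64718, too close to that gain to exclude it. Both explanations stay open without sequences or the counting rules.

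A hypothesis for miR395a and miR399 is a lower nutrient supply, since drought pots also received less fertilizer and both families are known to rise in plants short of sulfate or phosphate. Of the other tested members of the list, miR399b and miR827, 0 passed: miR399b stood at 1.86 ± 0.60 (edgeR adjusted p = 0.0529) and miR827 at 0.95 ± 0.67 (0.313), with 39.9, 61.6 and 7.01 CPM in drought, the last below every control library. For miR399, reads traded with miR399b are argued against, since the summed counts of the family rose by 1.98 on the log2 scale, while family miR395 has 1 listed member and gives no such test. Water and fertilizer were reduced in the same pots, so the contributions of the 2 cannot be told apart here. Pots given weekly water with full fertilizer, or full water with weekly fertilizer, would separate them.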
